A study of Mus musculus with 6 samples.

How the data were processed

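Liver RNA of mice was extracted with Trizol and a Zymo Direct-zol kit and treated with DNase. Stranded total RNA libraries depleted of ribosomal RNA were made with an Illumina kit (RiboZero Plus) from 100 ng of RNA, per the labels. The deposited values are raw counts per Ensembl gene, and the submitters' processing notes name the genome build mm10. The aligner, the counting tool and its strand setting are not given in the sources used here. The table held 43346 genes and 6 libraries, 3 per group, with no columns of other samples. Groups were taken from the labels: S100a11 shRNA 2, 3 and 2600, and scrambled shRNA 28, 30 and 31, all on the FFC diet.

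By Ensembl identifier 42462 genes matched the GENCODE M21 annotation, which supplied symbols, and 3370 symbols differed from those in the table. Coordinates were identical for 33497 genes. All 37 mitochondrial genes held 0 counts in every library of this total RNA, so they seem not to have been counted or to have been removed from the table, and the list of mitochondrially encoded genes could not be tested. The gene Gm20425, which overlaps Trf, held 97.6% to 98.7% of the Trf count, so reads in overlapping genes seem to have been counted more than once. Every pair of libraries differed beyond sampling noise (chi-square per gene of at least 48.4 over genes with at least 20 counts in the pair).

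Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 19352 genes and at least 99.95% of the counts of each library. TMM factors were 0.822 to 0.932 in the libraries labelled S100a11 shRNA and 1.10 to 1.19 in the scrambled libraries. The groups were compared with the quasi-likelihood F test (glmQLFit, glmQLFTest), with Benjamini-Hochberg adjustment over tested genes and a threshold of 0.05. The common biological coefficient of variation was 0.223. CPM are counts relative to the TMM-scaled library total, from edgeR's cpm function, and principal components used log2 CPM with a prior count of 2. S100a11 was also compared by an exact permutation test. Poisson intervals at 95% cover counting error only. Depth was 53517387 to 78091845 counts per library.

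The design, the 37 gene lists, the tests and most alternatives were fixed before the data were examined. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and adjustment over lists. Camera with an estimated correlation and fry were run beside it. Named genes were S100a11, the 12 largest rises and 12 largest falls among genes past the threshold, the first 4 members by p of each described list, and sex-linked genes. The largest changes had to have a mean of at least 2 CPM, no overlap between groups and a symbol other than a predicted model or clone. Other members are named with a statement that they were chosen after their values were seen. Some genes that the rule names are not reported here.

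Alternatives were RLE and upper-quartile factors, no filter, at least 1 CPM in 3 libraries, leaving out the 20 most abundant genes, named genes only, leaving out each library in turn, DESeq2 1.42.0, limma voom with and without quality weights, a robust prior, the legacy quasi-likelihood, an adjusted p of 0.1, glmTreat against 1.5-fold, and cameraPR. Scaling by library totals alone, and counts of list members without library 2 or library 2600, were added after seeing the data. Tables and figures used python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

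The procedure was tested on simulated data of the same depth and spread, with 200 genes changed and 19037 tested. It called 2.99% of genes changed 1.5-fold, 40.3% of those changed 2-fold and 90.9% of those changed 4-fold. Of 99 calls 10.1% were unchanged genes, and in 10 further simulations 9.55% of 859 calls, above the nominal 5%. With no gene changed edgeR called 0 of 19051 genes. With 200 changed genes the adjusted threshold is stricter than with the 2728 genes called in the data. The shares called are therefore not the sensitivity of the comparison of the libraries.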

Results

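RNA was sequenced from whole livers of mice that all received the FFC diet, a diet used to model metabolic dysfunction-associated steatohepatitis, together with an adeno-associated virus 8 carrying a short hairpin RNA (shRNA). In 3 libraries the label names an shRNA against S100a11, a calcium-binding protein of the S100 family, and in 3 libraries a scrambled shRNA. The comparison asks how silencing S100a11 alters liver transcripts in this dietary model. The libraries labelled S100a11 shRNA 2, 3 and 2600 held 69257299, 69874237 and 53517387 counts over genes. The scrambled libraries 28, 30 and 31 held 61121177, 57717111 and 78091845. Nothing in the labels says that the samples are separate animals, so p-values measure the spread between samples.

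S100a11 was lower than in every scrambled library in 2 of the 3 libraries labelled S100a11 shRNA. The gene (ENSMUSG00000027907) lies on the plus strand of chromosome 3 from 93520488 to 93526287 in mm10. It stood at 3.55 CPM (counts scaled to the size of the library) in library 3 and 3.41 in library 2600, which is 15.5% and 14.9% of the scrambled mean. In the library labelled S100a11 shRNA 2 it stood at 16 CPM, level with the lowest scrambled library, number 28, at 15.9 CPM. Scrambled libraries 30 and 31 held 22.9 and 30.0 CPM. The group means were 7.65 ± 7.23 and 22.9 ± 7.08 CPM (SD, n = 3 each), a log2 change of -1.57 ± 0.56 (SE) that did not pass the threshold (edgeR adjusted p = 0.095). Without the library labelled S100a11 shRNA 2 the S100a11 change was -2.75 with an edgeR adjusted p of 0.00044. An exact two-sided permutation test of log2 S100a11 CPM gave p = 0.2, where 0.1 is the smallest p that 3 against 3 samples allow. Each direction below is therefore that of the libraries labelled S100a11 shRNA, of which library 2 had S100a11 at the level of the lowest scrambled library.

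**Figure D1:**
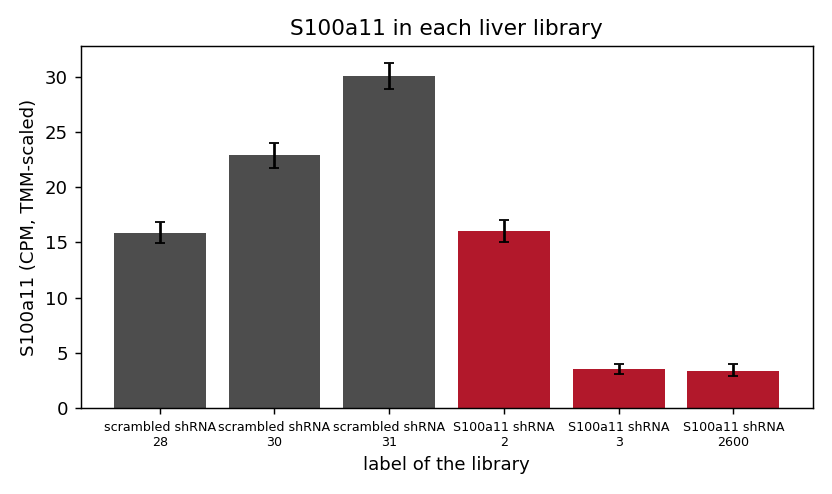
S100a11 level in CPM after TMM scaling (y axis, from 0) in each of the 6 libraries (x axis, by label); bars are single libraries, and error bars are 95% Poisson intervals that cover counting error only. The libraries labelled S100a11 shRNA 3 and 2600 sit at 3.55 and 3.41 CPM, while library 2 sits at 16 CPM, within the range of the scrambled libraries, 15.9 to 30.0 CPM.

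Expression differed widely between the groups. Of 19352 genes tested, 1126 were higher and 1602 lower in the libraries labelled S100a11 shRNA at an edgeR adjusted p under 0.05. In 34.7% of tested genes the groups did not overlap, against 10% by chance. With upper-quartile factors the split was 816 higher and 1980 lower, and with library totals alone, a choice made after seeing the data, 397 higher and 3970 lower. The median log2 change of all genes was 0.04 with TMM and -0.32 with library totals alone. The total of 2728 genes became 4176 without the library labelled S100a11 shRNA 2, and 1012 without library 3. Without scrambled libraries 28, 30 and 31 it became 1538, 724 and 1090. The first principal component held 55.6% of the variance and separated the groups, with scores of -24.7, -61.1 and -62.3 in libraries 2, 3 and 2600 against 41.1 to 54.8 in the scrambled libraries.

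The libraries also differed in composition. The non-coding gene Gm26917 took 3.99%, 6.44% and 10.8% of counts in libraries 2, 3 and 2600, against 4.08%, 4.42% and 3.16% in scrambled libraries 28, 30 and 31. Protein-coding genes held 90.9%, 87.1% and 81.7% against 90.1%, 89.2% and 91.5%. Genes with at least 1 count numbered 22893 to 24424 in the first group and 24713 to 25649 in the scrambled group. The median log2 change climbed with abundance, from -0.24 in the least abundant sixth of tested genes to 0.24 in the most abundant. All 6 libraries carried male transcripts: the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty lay between 42.2 and 110.1 CPM in every library, and Xist, which marks the inactive X, lay at or below 0.70 CPM.

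The largest fall among genes with a mean of at least 2 CPM named by size of change was that of Fbn2. This gene, which encodes an elastic microfibril protein, was 33.0-fold lower (0.28 ± 0.097 against 9.21 ± 3.76 CPM, SD, n = 3 each, adjusted p = 0.0023). Mmp7, a metalloproteinase of duct epithelium, was 11.6-fold lower (adjusted p = 0.0068), Itgb6, the epithelial integrin that activates TGF-beta, 10.4-fold lower (adjusted p = 0.0032) and Cftr, the chloride channel of bile ducts, 8.51-fold lower (adjusted p = 0.0060). The other named falls were Cfap44, Myh15, Gipc2, Adamts16, Shc2, Scube3, Ly6d and H2-M2, from 8.04-fold to 28.0-fold lower. Ly6d stood at 6.44 ± 6.44 against 58.3 ± 8.08 CPM (adjusted p = 0.013). Without the library labelled S100a11 shRNA 2 the log2 changes of Cfap44, Gipc2 and Ly6d went from -4.81, -4.09 and -3.17 to -6.07, -4.69 and -4.46. Without scrambled library 30 those of Cfap44 and Mmp7 were -4.19 and -2.83, the latter from -3.54, and without library 2600 that of Scube3 went from -3.35 to -3.94.

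Major urinary protein genes, whose products are secreted mainly by the male liver, made up 9 of the 12 largest rises among named genes. Mup7, Mup11, Mup15, Mup14, Mup1, Mup17, Mup12, Mup9 and Mup8 were 17.9-fold to 419-fold higher. They lie on chromosome 4 and are near-identical copies, so how reads were divided among them is uncertain. Without library 2600 the log2 changes of Mup7, Mup14, Mup17 and Mup8 went from 8.71, 5.68, 5.29 and 4.16 to 7.94, 4.96, 4.59 and 3.54, and without scrambled library 28 that of Mup8 was 4.94. How reads that match several copies were counted is not given, which leaves their sum uncertain too. The summed CPM of 21 Mup genes was 2.86-fold higher (5764 ± 2336 against 2017 ± 272 CPM, SD, n = 3 each), and was 3222, 6253 and 7817 CPM in libraries 2, 3 and 2600. The other large rises were the hepatic organic anion carrier Slco1a1 (146 ± 97.0 against 7.86 ± 3.12 CPM, adjusted p = 0.0059), the calpain Capn8 (21.5-fold, adjusted p = 0.0049) and the steroid dehydrogenase Hsd3b5. Hsd3b5 stood at 9.94 ± 12.8 against 0.13 ± 0.019 CPM (adjusted p = 0.019). Its log2 change of 6.29 was 4.31 without library 3, and its adjusted p was 0.060, 0.080 and 0.064 without scrambled libraries 28, 30 and 31. Mup8 had an adjusted p of 0.051 without library 3, 0.063 without scrambled library 30 and 0.052 without scrambled library 31.

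Gene lists written before the data were examined grouped the changes, and 36 of 37 could be tested. At a preset correlation of 0.01, camera called 25 lists, 12 upward and 13 downward, after adjustment over lists. None passed with an estimated correlation, where the smallest adjusted p was 0.36 and 2 lists had an unadjusted p under 0.05, and 8 passed with fry. The same test called 9 to 23 lists in the other 9 ways of dividing the 6 libraries into groups of 3, in which edgeR and limma voom each called 0 genes (95 to 1801 by edgeR at an unadjusted p under 0.05).

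Macrophage genes of the monocyte-derived, lipid-associated kind were lower throughout. Of 26 tested members 20 fell and 0 rose (23 fell when adjusted over the list alone), with a median log2 change of -1.45 (camera adjusted p = 2.83e-15, adjusted p = 0.36 with an estimated correlation). Trem2, the lipid receptor of these cells, was 4.57-fold lower (5.58 ± 1.96 against 25.6 ± 3.11 CPM, SD, n = 3 each, adjusted p = 0.0032). Spp1, encoding osteopontin, was 5.90-fold lower (43.8 ± 17 against 258 ± 54.9 CPM, adjusted p = 0.0032), Lpl, lipoprotein lipase, 4.80-fold lower and the tetraspanin Cd9 2.83-fold lower. Some members are shared between lists: Spp1 is also in the ductular list, Mmp12 in the matrix list and Lpl among lipid uptake genes. Markers of resident Kupffer cells were not called as a group (camera adjusted p = 0.69, adjusted p = 0.94 with an estimated correlation). Of 20 members 1 rose and 1 fell, and by sign alone 8 were higher and 12 lower. The list median was -0.15 and its mean 0.29, and camera gave it a downward sign. Cd163 and Marco, chosen after their values were seen, raised the mean (log2 changes 3.50 and 3.17) without passing the threshold. They stood at 27.8 and 20.6 CPM in library 2600 but at 0.57 and 0.62 CPM in library 2. With library totals alone 1 Kupffer member rose and 6 fell, with a median of -0.51, or -0.19 relative to all genes with either scaling. Timd4, the phosphatidylserine receptor of resident Kupffer cells, rose 4.98-fold (8.89 ± 1.56 against 1.78 ± 0.53 CPM, adjusted p = 0.0033). C1qb fell 1.91-fold (adjusted p = 0.036), a call that ended without any one of libraries 3, 2600, 28, 30 or 31 (adjusted p of 0.071 to 0.12). Without the library labelled S100a11 shRNA 2, 5 Kupffer members rose and 2 fell.

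Extracellular matrix genes fell together. Of 35 members 25 fell and 0 rose (29 adjusted over the list alone), with a median log2 change of -1.24 (camera adjusted p = 5.62e-15, adjusted p = 0.36 with an estimated correlation). Elastin, Eln, was 3.26-fold lower (5.23 ± 0.62 against 17 ± 1.17 CPM, SD, n = 3 each, adjusted p = 0.0025) and fibrillin 1, Fbn1, 2.26-fold lower (adjusted p = 0.0050). The basement membrane collagen Col4a2 was 2.26-fold lower (adjusted p = 0.0035) and its neighbour Col4a1 2.17-fold lower, although these genes overlap and may share reads. Of 19 stellate cell and myofibroblast markers 8 fell and 0 rose (9 adjusted over the list alone), with camera adjusted p = 6.65e-05 and adjusted p = 0.41 with an estimated correlation. The platelet-derived growth factor receptors Pdgfrb and Pdgfra were 2.46-fold and 2.14-fold lower (adjusted p = 0.0037 and 0.0054), and Tgfb2 2.80-fold lower. Without library 2600, the library with the highest Gm26917 share, 15 matrix genes and 5 stellate genes fell, and with library totals alone 13 stellate genes fell.

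Ductular genes showed the lowest median of the called lists. Of 19 cholangiocyte and ductular markers 15 fell and 1 rose (17 and 2 adjusted over the list alone), with a median log2 change of -1.91 (camera adjusted p = 6.12e-11, adjusted p = 0.36 with an estimated correlation). Pkhd1, the fibrocystin gene of bile duct cilia, was 2.99-fold lower (75.3 ± 9.47 against 225 ± 25.6 CPM, SD, n = 3 each, adjusted p = 0.0028). Among 24 YAP and TAZ target genes 10 fell and 0 rose, also 10 adjusted over the list alone (camera adjusted p = 0.0029, adjusted p = 0.36 with an estimated correlation), and 6 fell without library 2600. Ankrd1 was 11.9-fold lower (0.25 ± 0.17 against 2.78 ± 1.17 CPM, adjusted p = 0.0049) and Ajuba 2.39-fold lower (adjusted p = 0.0051). In the S100 and annexin family, which does not include S100a11 here, 5 of 18 members fell and 0 rose (7 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.0042, adjusted p = 0.45 with an estimated correlation). Anxa3 and Anxa1 were 2.16-fold and 2.39-fold lower (adjusted p = 0.0070 and 0.0085). Without the library labelled S100a11 shRNA 2, 9 members fell.

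Genes of other immune cells fell in smaller numbers. Over all 19352 tested genes 14.1% passed the threshold in either direction, and 1602 fell. Small counts of falls, such as those of T and NK and of B cell markers, are to be read against these 1602 of 19352 genes. The 14.1% includes rises. Cytokines and chemokines gave 6 falls and 0 rises of 35 (9 falls adjusted over the list alone), with camera adjusted p = 6.65e-05 and adjusted p = 0.41 with an estimated correlation. They included the monocyte attractant Ccl2, 2.76-fold lower (1.92 ± 0.41 against 5.31 ± 1.38 CPM, SD, n = 3 each, adjusted p = 0.010), and Cxcl14, 3.72-fold lower (adjusted p = 0.0069). T and NK cell markers gave 3 falls of 26, also 3 adjusted over the list alone (camera adjusted p = 0.00079, adjusted p = 0.43 with an estimated correlation), led by the interleukin 7 receptor Il7r, 2.73-fold lower (adjusted p = 0.0051). Another of the 3, Foxp3, overlaps far more abundant genes and is uncertain. B and plasma cell markers gave 2 of 18, also 2 adjusted over the list alone (camera adjusted p = 0.0042, adjusted p = 0.41 with an estimated correlation), and the immunoglobulin gene Ighm was 3.09-fold lower (adjusted p = 0.011). Neutrophil markers gave 3 of 12 (4 falls and 1 rise adjusted over the list alone, camera adjusted p = 0.0026, adjusted p = 0.43 with an estimated correlation). Without library 2600, 5 neutrophil genes fell. Ngp and Mpo, among the 3 falls, lay near the floor, with scrambled means of 0.52 and 0.45 CPM. Lcn2, which hepatocytes also make, was 3.37-fold lower (50.5 ± 15.6 against 170 ± 10.4 CPM, adjusted p = 0.0045). Dendritic cell and antigen presentation markers gave 6 of 17 (8 falls and 1 rise adjusted over the list alone, camera adjusted p = 0.0026, adjusted p = 0.41 with an estimated correlation). Cd74, the class II invariant chain, was 2.27-fold lower (adjusted p = 0.021), but not without library 3, 2600, 30 or 31 (adjusted p of 0.053 to 0.076). Without the library labelled S100a11 shRNA 2 the falls numbered 13 cytokine, 8 T and NK and 9 dendritic genes, and without library 2600 they numbered 5, 1 and 2. With library totals alone the falls numbered 16 cytokine, 9 T and NK, 6 B cell and 6 neutrophil genes.

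Among liver endothelial markers the balance of calls depended on the scaling. Of 21 members 6 rose and 2 fell with TMM (10 and 3 adjusted over the list alone), and 3 rose and 4 fell with library totals alone, with camera adjusted p = 0.00615 and adjusted p = 0.41 with an estimated correlation. The median log2 change was 0.35 with TMM and -0.03 with library totals alone, and 0.31 and 0.28 relative to the median of all genes. Wnt2, a ligand made by central endothelium, was 2.63-fold higher (3.48 ± 0.35 against 1.32 ± 0.28 CPM, SD, n = 3 each, adjusted p = 0.0083), and the sinusoidal lectin Clec4g 1.76-fold higher (adjusted p = 0.011, or 0.055 without scrambled library 30). Without library 2600, 4 members rose and 0 fell.

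**Figure D2:**
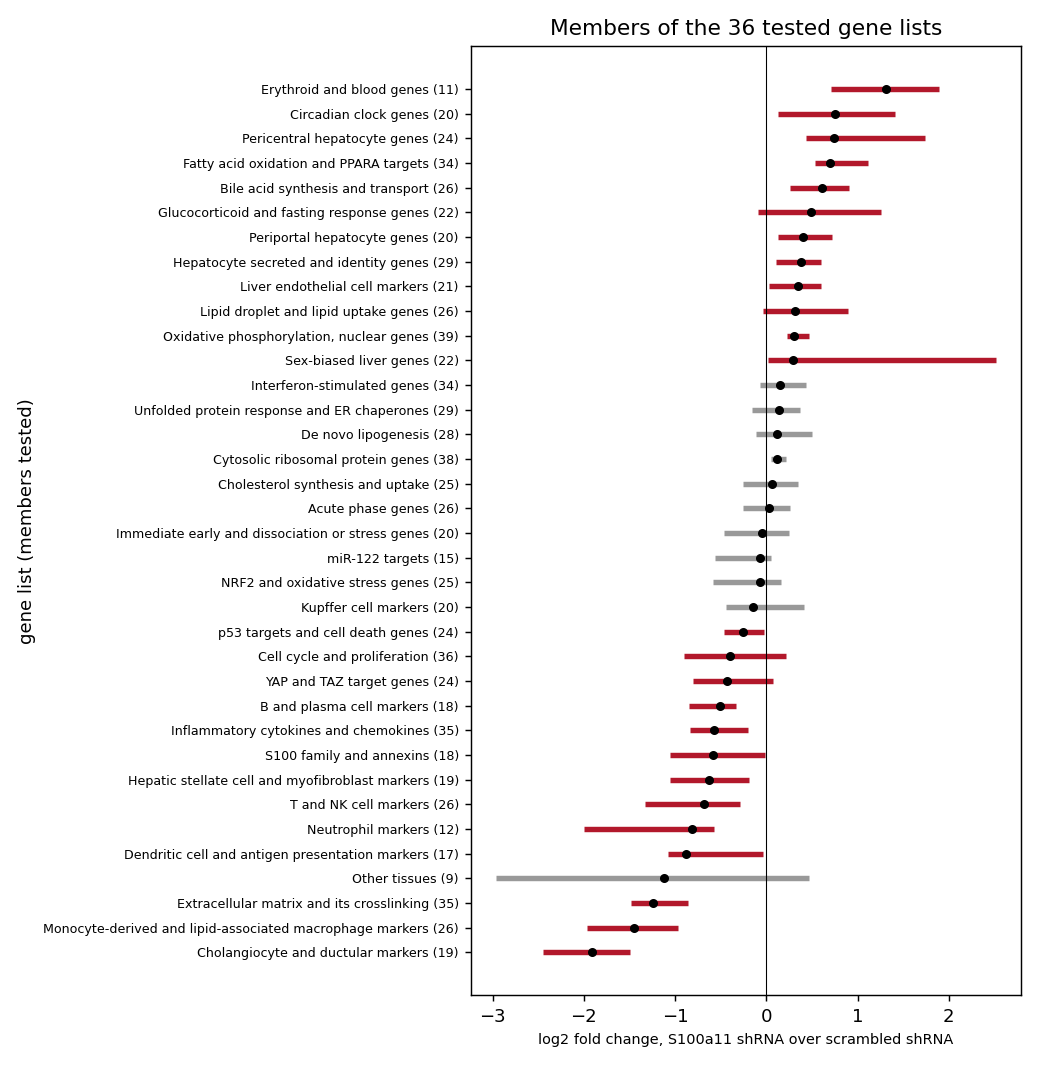
Log2 fold changes of list members, libraries labelled S100a11 shRNA over scrambled (x axis), for the 36 tested lists (y axis, with members tested); points are medians, bars span the quartiles, red marks a camera adjusted p under 0.05 at the preset correlation and grey the others. Ductular, macrophage and matrix lists have medians of -1.91, -1.45 and -1.24 and pericentral and fatty acid oxidation lists 0.74 and 0.70, while 10 of the medians above 0, the endothelial 0.35 among them, lie below 0 with library totals alone.

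Hepatocyte genes of fat oxidation and of the pericentral zone were higher, more of them with TMM than with library totals alone. Of 34 fatty acid oxidation and PPARA target genes 18 rose and 1 fell (26 and 1 adjusted over the list alone), with a median log2 change of 0.70 (camera adjusted p = 8.99e-12, adjusted p = 0.36 with an estimated correlation). With library totals alone 9 rose, with a median of 0.35. Acot1, an acyl-CoA thioesterase, was 5.83-fold higher (52.5 ± 18.8 against 9.0 ± 1.71 CPM, SD, n = 3 each, adjusted p = 0.0030). The peroxisome gene Pex11a was 2.24-fold higher (adjusted p = 0.0060) and the carnitine carrier Slc25a20 1.83-fold higher (adjusted p = 0.0064). Fgf21, a secreted stress and PPARA-regulated hormone, fell 2.87-fold (adjusted p = 0.0069). Of 24 pericentral genes 12 rose and 0 fell (15 adjusted over the list alone), with a median log2 change of 0.74, or 0.38 with library totals alone (camera adjusted p = 4.52e-08, adjusted p = 0.41 with an estimated correlation). Cyp2e1, the ethanol-metabolising P450, was 3.33-fold higher (6953 ± 1863 against 2089 ± 210 CPM, adjusted p = 0.0090), and the glutamate transporter Slc1a2 3.81-fold higher (adjusted p = 0.0032). Of 20 periportal genes 4 rose and 1 fell, likewise adjusted over the list alone (camera adjusted p = 0.0026, adjusted p = 0.41 with an estimated correlation). Without the library labelled S100a11 shRNA 2 the list was not called (adjusted p = 0.072) and 3 members fell. The urea cycle gene Asl was 2.13-fold higher (adjusted p = 0.0060). The periportal median was 0.40 with TMM and 0.05 with library totals alone, or 0.36 relative to all genes with either. The gluconeogenic gene Pck1 was 3.16-fold higher (adjusted p = 0.0093). Pck1, G6pc and Tat, all among the periportal rises, are also in the glucocorticoid and fasting list, and Tat in the hepatocyte identity list. Rises in these lists are therefore not separate findings.

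Secreted and identity genes of hepatocytes gave 6 rises of 29 and 0 falls (10 adjusted over the list alone, camera adjusted p = 5.16e-06, adjusted p = 0.36 with an estimated correlation), and 2 rises with library totals alone. Their median was 0.38 with TMM and 0.03 with library totals alone, or 0.34 and 0.35 relative to all genes. The antitrypsin gene Serpina1c, 1 of a family of close copies and so uncertain, was 2.87-fold higher (891 ± 145 against 310 ± 28.9 CPM, SD, n = 3 each, adjusted p = 0.0035). Bile acid synthesis and transport gave 11 rises of 26 and 0 falls (15 adjusted over the list alone), with a median log2 change of 0.61 (camera adjusted p = 1.66e-06, adjusted p = 0.36 with an estimated correlation). With library totals alone 5 rose, with a median of 0.25, and without the library labelled S100a11 shRNA 2 the list had 2 falls. Cyp8b1, the sterol 12-alpha-hydroxylase, was 2.66-fold higher (380 ± 129 against 143 ± 13 CPM, adjusted p = 0.0079) and Cyp7b1, of the alternative pathway, 6.05-fold higher (156 ± 106 against 25.8 ± 1.87 CPM, adjusted p = 0.0079), with a log2 change of 2.60, or 1.91 without library 3. The bile acid uptake carrier Slc10a1 was 1.94-fold higher (adjusted p = 0.010, or 0.056 without scrambled library 30).

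Lipid storage and synthesis genes were divided. Of 26 lipid droplet and uptake genes 10 rose and 3 fell (11 and 3 adjusted over the list alone), and 6 rose and 4 fell with library totals alone, with camera adjusted p = 0.0069 and adjusted p = 0.41 with an estimated correlation. Their median was 0.32 with TMM and -0.05 with library totals alone, or 0.28 and 0.27 relative to all genes. Fitm2, needed for droplet budding, was 2.12-fold higher (130 ± 21.3 against 61.1 ± 9.99 CPM, SD, n = 3 each, adjusted p = 0.0077), while Lpl fell. Lipogenesis genes were not called as a list (adjusted p = 0.14, or 0.74 with an estimated correlation), with 4 rises and 1 fall of 28, likewise adjusted over the list alone. Its median was 0.12 with TMM and -0.22 with library totals alone, where 1 gene rose and 3 fell. That list passed without library 2600 (adjusted p = 0.018, with 0 falls), and without the library labelled S100a11 shRNA 2 it had 3 falls. Thrsp, a lipogenic regulator, rose 3.32-fold (adjusted p = 0.013). Cholesterol synthesis genes were not called either (adjusted p = 0.90, or 0.97 with an estimated correlation), with 1 rise and 3 falls of 25, likewise adjusted over the list alone, and 1 fall without library 2600. Of the 3 falls that of Mvd is uncertain, as it overlaps a more abundant gene. The list median was 0.06 and its mean -0.06 with TMM, camera gave it an upward sign, and the median was -0.03 with upper-quartile factors and -0.28 with library totals alone. Hmgcs1, an enzyme of the mevalonate pathway, fell 1.81-fold (adjusted p = 0.043), but not without library 3, 28, 30 or 31 (adjusted p of 0.064 to 0.12).

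**Figure D3:**
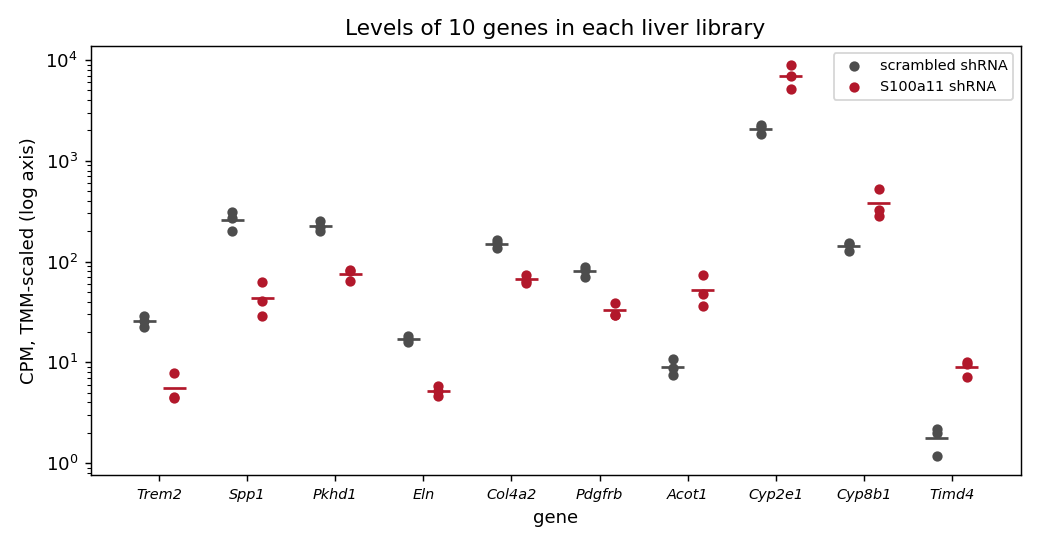
CPM after TMM scaling on a log axis (y axis) of 10 genes (x axis) in the 6 libraries; points are single libraries, red for the label S100a11 shRNA and grey for scrambled, and lines are means of 3. Trem2, Spp1, Pkhd1, Eln, Col4a2 and Pdgfrb lie lower in the libraries labelled S100a11 shRNA, as in Trem2 at 5.58 against 25.6 CPM, and Acot1, Cyp2e1, Cyp8b1 and Timd4 lie higher, with no overlap in any of these genes.

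Male-predominant liver genes rose beyond the Mup family. Of 22 tested sex-biased genes 7 rose and 1 fell (10 and 2 adjusted over the list alone), and 7 rose and 3 fell with library totals alone, with camera adjusted p = 0.0064 and adjusted p = 0.41 with an estimated correlation. The median was 0.29 with TMM and -0.08 with library totals alone, or 0.25 and 0.24 relative to all genes. This list also holds female-predominant genes, Xist, Y-linked genes and Mup20, so these values are not those of male-predominant genes alone. Its members Slco1a1 and Cyp7b1 are in the bile acid list too. Elovl3, a fatty acid elongase, was 12.3-fold higher (146 ± 107 against 11.9 ± 3.90 CPM, SD, n = 3 each, adjusted p = 0.0067), with a log2 change of 3.62, or 2.87 without library 2600, and the P450 gene Cyp2d9, which has close copies, 4.10-fold higher (adjusted p = 0.0083).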

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

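Scaling by library totals alone was chosen after the result was seen. No called result among the 110 called genes named by the rule and the 25 called lists reversed. Of these, 98 genes and 24 lists passed with every scaling, and 75 genes and 22 lists passed without each single library. Camera compares list members with the other genes, so a scaling that shifts all genes alike barely bears on its calls. The genes were chosen by p or size of change in these same data, so a reversal was unlikely from the start. The gene count of 2728 became 4367 with library totals alone, 4206 at an adjusted p of 0.1 and 616 with glmTreat, which tests against 1.5-fold. Calls were 58.7% lower with TMM, 70.8% with upper-quartile factors and 90.9% with library totals alone. Leaving out single libraries gave 724 to 4176 genes, 24 to 26 lists and an S100a11 change of -2.75 to -1.22. The S100a11 change passed at -1.90 with library totals alone, -1.89 with voom and -2.24 with quality weights, and at -1.57 under the threshold of 0.1. Its adjusted p ranged from 0.00044 to 0.32. List calls numbered 0 with an estimated correlation and 8 with fry, and 23 to 27 under the other settings that kept all libraries. No paired analysis was possible because the sample numbers do not repeat across groups. Calls of Agpat2, Cxcl16, Ciita and Rhbg, counted in their lists, are uncertain, as overlapping genes held 83.7%, 85.1%, 71.5% and 104% of their counts. Rpl18 and Cela2a, among others, also overlap expressed genes (Sphk2 at 216% and Casp9 at 6847% of their counts).

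Of the lists that were not called, 7 changed sign under some setting, with the adjusted p given here. Kupffer markers had 0.78 with cameraPR, cholesterol synthesis 0.87 with the filter at 1 CPM and 0.99 with fry. With library totals alone NRF2 genes had 0.99 and other tissues 0.98. Leaving out single libraries turned Kupffer (without 3 or 28), cholesterol (2, 3 or 30), NRF2 (3, 2600 or 28), acute phase (3), ribosomal protein (2) and immediate early genes (3). Over all 6 leave-outs, those that kept the sign included, the adjusted p spanned 0.13 to 0.94 for Kupffer, 0.077 to 0.95 for cholesterol, 0.077 to 0.77 for NRF2, 0.078 to 0.99 for acute phase, 0.0022 to 0.39 for ribosomal protein and 0.077 to 0.79 for immediate early genes. The cause was not tested. With 3 libraries per group and 200 changed genes, far fewer than were called in the data, 40.3% of simulated changes of 2-fold were called.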

Other observations

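The tests of the macrophage, matrix and ductular fall, the test of summed Mup levels, the test of hepatocyte share, the counts over other splits, and the list counts without library 2 or 2600 or with library totals alone were chosen after the result was seen. Circadian clock genes shifted in the libraries labelled S100a11 shRNA: 7 of 20 rose and 1 fell (11 and 2 adjusted over the list alone), with camera adjusted p = 0.0011 and adjusted p = 0.36 with an estimated correlation. The clock repressor Cry1 was 4.27-fold higher (26.8 ± 9.92 against 6.26 ± 0.967 CPM, SD, n = 3 each, adjusted p = 0.0037), and the repressor Per2 2.99-fold higher (adjusted p = 0.0079). The member that fell, chosen after its values were seen, was Npas2 (log2 change -2.76, adjusted p = 0.031). Without library 2600, 11 clock genes rose, and with library totals alone 4 rose and 2 fell. The labels give no batch or day, and the sample titles give no hour of collection or feeding state. A difference in any of these between the groups was not tested as a cause, here or for the metabolic genes above. Glucocorticoid and fasting response genes gave 8 rises and 1 fall of 22 (9 and 1 adjusted over the list alone, camera adjusted p = 0.00615, adjusted p = 0.41 with an estimated correlation). The gluconeogenic gene G6pc was 3.00-fold higher (adjusted p = 0.011), while Lcn2 fell, and without the library labelled S100a11 shRNA 2 the list had 3 falls. With library totals alone it had 4 rises and 3 falls. Nuclear genes of oxidative phosphorylation gave 6 rises and 0 falls of 39, likewise adjusted over the list alone (camera adjusted p = 5.16e-06, adjusted p = 0.52 with an estimated correlation). Their median was 0.31 with TMM and -0.04 with library totals alone, where 0 rose, and 1 rose without library 2600. Erythroid genes gave 2 rises and 0 falls of 11 (4 and 1 adjusted over the list alone, camera adjusted p = 0.0042, adjusted p = 0.45 with an estimated correlation), and 1 rose without library 2, without library 2600, or with library totals alone. Of the 2 erythroid rises that of Alas2 is uncertain, as it overlaps Apex2. The erythroid list was not called with the filter at 1 CPM (adjusted p = 0.055).

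Cell cycle genes gave 2 rises and 7 falls of 36 (2 and 8 adjusted over the list alone, camera adjusted p = 0.0095, adjusted p = 0.74 with an estimated correlation). Both rises, Tk1 and Ccne2, and the fall of Kif20a are uncertain, as these genes overlap more abundant ones whose reads may be counted for them (Afmid holds 392% of the Tk1 counts, Ints8 1657% of the Ccne2 counts and Cdc23 499% of the Kif20a counts). The kinetochore motor Cenpe was 2.85-fold lower (3.8 ± 1.02 against 10.9 ± 1.42 CPM, SD, n = 3 each, adjusted p = 0.0059). The cell cycle list was not called without library 3 (adjusted p = 0.16) or library 2600 (adjusted p = 0.13, with 3 falls), and 18 members fell without the library labelled S100a11 shRNA 2. Nor was it called with library totals alone (adjusted p = 0.15) or with cameraPR (adjusted p = 0.082). The p53 and cell death list gave 1 rise and 2 falls of 24, likewise adjusted over the list alone (camera adjusted p = 0.045, adjusted p = 0.45 with an estimated correlation). It was not called without library 3, 2600, 28 or 31 (adjusted p of 0.19, 0.072, 0.12 and 0.084), nor with cameraPR (adjusted p = 0.11), and had 6 falls without library 2, 3 without library 2600 and 11 with library totals alone. Among acute phase genes 2 of 26 rose and 4 fell, likewise adjusted over the list alone, with Saa2 2.34-fold lower and Saa4 2.36-fold higher (adjusted p = 0.0035 and 0.0051). That list was not called (camera adjusted p = 0.47), with a median of 0.03, a mean of -0.09, a downward sign from camera, and medians of -0.06 with upper-quartile factors and -0.33 with library totals alone, where 1 rose and 8 fell.

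Of the other lists that were not called, unfolded protein response genes gave 3 rises and 3 falls of 29 (4 and 3 adjusted over the list alone, camera adjusted p = 0.43), with a median of 0.14, or -0.22 with library totals alone, where 0 rose and 7 fell. NRF2 genes gave 0 rises and 1 fall of 25 (0 adjusted over the list alone, camera adjusted p = 0.74), with 6 falls without library 2 and 3 with library totals alone. Interferon-stimulated genes gave 2 rises and 1 fall of 34 (0 adjusted over the list alone, camera adjusted p = 0.13), with a median of 0.15, or -0.19 with library totals alone, where 0 rose and 3 fell, and the list passed without library 2600 (adjusted p = 0.015) or 31 (adjusted p = 0.017). Both of its rises, Irf7 and Gbp3, are uncertain, as each overlaps another expressed gene. Ribosomal protein genes gave 1 rise and 0 falls of 38 (0 adjusted over the list alone, camera adjusted p = 0.084), with a median of 0.12, or -0.23 with library totals alone, and passed without library 3, 2600 or 31 (adjusted p of 0.0055, 0.0073 and 0.0022) and with no filter (adjusted p = 0.040), while camera gave a downward sign without library 2 (adjusted p = 0.39). Targets of miR-122 gave 1 rise and 2 falls of 15 (2 and 5 adjusted over the list alone, camera adjusted p = 0.30), with 5 falls without library 2 or with library totals alone. Genes of other tissues gave 1 rise and 2 falls of 9 (1 and 4 adjusted over the list alone, camera adjusted p = 0.31), with 4 falls with library totals alone, and passed without library 3 (adjusted p = 0.043) or 30 (adjusted p = 0.013) and with no filter (adjusted p = 0.027). Of its falls that of Vil1 is uncertain, as it overlaps the more abundant Usp37. Immediate early genes gave 3 rises and 3 falls of 20, likewise adjusted over the list alone (camera adjusted p = 0.45), with 5 falls without library 2 and 7 with library totals alone.

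For the scrambled level of S100a11 in the library labelled S100a11 shRNA 2, more RNA from macrophage, ductular and stellate cells is argued against. S100a11 was 4.60 times the mean of libraries 3 and 2600. The 63 markers of these cells had a median ratio of 1.38 and a 90th percentile of 1.95, and 0 had a higher ratio than S100a11. Other non-hepatocyte cells were not covered by this test. A scrambled sample under a wrong label is argued against: on a scale from 0 (scrambled) to 1 (libraries 3 and 2600), its median position over 4118 genes was 0.587, above the bound of 0.5 and above the held-out scrambled libraries at 0.193, 0.0198 and -0.0471, both set before the result was seen. It lay 0.394 above the highest of these, whose range was 0.24, a spread chosen after the result was seen, although its quartiles over genes (0.286 and 0.882) overlap those of library 28 (0.029 and 0.342). Over all genes library 2 differed less from the scrambled libraries (chi-square per gene of 193, 223 and 158) than from libraries 3 and 2600 (235 and 349), but scrambled pairs differed by 48.4 to 75.2. Weak silencing in that sample and a sample from outside these groups stay open and were not tested.

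Macrophage, matrix and ductular genes fell in the libraries labelled S100a11 shRNA. A lower share of all non-hepatocyte RNA alike is argued against as the whole cause, since the lower quartile of endothelial changes, 0.03, lay 1.003 above the upper quartile of macrophage changes, -0.97. The choice among 5 scalings is argued against too, as it is too small to make the fall. These scalings put the median of all genes between -0.32 and 0.04. The upper quartile of 78 members was at most -0.92 over them and with the median of genes of like abundance subtracted. Library 2, with S100a11 at the scrambled level, showed the fall too, with Trem2 at 7.84 CPM against 22.4 to 28.6 and Pkhd1 at 64.4 against 202 to 252 in the scrambled libraries. Its Gm26917 share was 3.99%, within the scrambled range of 3.16% to 4.42%. Trem2 and Pkhd1 were thus lower in library 2 without a higher Gm26917 share. Silencing of S100a11, the difference that the design names, and the higher Gm26917 share of libraries 3 and 2600 stay open and were not tested as causes.

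Mup and other male-predominant genes rose in the libraries labelled S100a11 shRNA. For the Mup genes the sum was 2.86-fold higher, at 3222 to 7817 CPM against 1708 to 2223 CPM in the scrambled libraries. How reads shared among copies were counted is not given. A higher total of Mup RNA therefore cannot be told apart from a shift in which copies are expressed. Which copy rose, and by how much, stays uncertain. For the other genes a higher hepatocyte share is argued against. Outside the Mup family 6 of 6 male-predominant genes rose, with a median of 3.11 and a lower quartile of 2.18. Both lie above the upper quartile of hepatocyte identity genes, 0.60. These 6 genes form a list apart from the 37, and Slco1a1 and Hsd3b5 among them were already named as large rises. The lowest of the 6 changes, that of Cyp4a12a, was 1.27. Higher growth hormone and STAT5 signalling stays open. Socs2, Cish and Igfals had a median of 0.59 and an upward fry p of 0.036. Only Igfals passed (log2 change 1.15, adjusted p = 0.0049), with Cish at 0.59 (adjusted p = 0.36) and Socs2 at 0.31 (adjusted p = 0.52). Cish and Socs2 were highest in library 2, at 40.878 and 32.824 CPM. There the male-predominant genes outside the Mup family were each lowest of the group labelled S100a11 shRNA. In library 3 Cish and Socs2 stood at 12.962 and 17.294 CPM, below scrambled libraries 30 and 31. Igfals instead was lowest of that group in library 2, at 112.75 CPM, and highest in library 3, at 149 CPM. Of 8 tested female-predominant genes edgeR called 0, and their fry p was 0.34.

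The 6 libraries can be divided into 10 splits, too few for a share under 0.05. The real split gave 2728 genes and the highest other 0, by edgeR and by limma voom, with 95 to 1801 genes at an unadjusted p under 0.05. It gave 25 lists and the highest other 23, and 1 split of 10, the real one, reached the real value in each case.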
